A study of Mus musculus with 53 samples.

How the data were processed

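The series holds 53 samples: 5 bulk RNA libraries, 2 chromatin precipitations, 45 single cells and 1 pool. Bulk RNA was made into libraries from total RNA with a TruSeq kit and read as single reads of 26 or 100 bp, per the labels; which library had which length is not given in the sources used here. Single cells came from a Fluidigm C1 chip and were made into libraries with Nextera XT, about 24 mixed per pool and read at 100 bp, per the labels. Tbx3 sites came from a streptavidin pull-down of biotin-tagged Tbx3 in N/N cells with the BirA ligase, with BirA-only cells as the control, per the labels; the control has no file of its own.

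The bulk values are FPKM, fragments scaled to transcript length and library total, which the authors made with TopHat, Cufflinks and Cuffdiff on mm9, per the submitters' processing notes. The single-cell values are FPKM scaled across libraries by the authors with TopHat and Cuffnorm, per the submitters' processing notes. Bulk and single-cell tables were scaled separately, so values are not comparable between them. FPKM scaling sets each library to its own total, so a gene that takes a larger share lowers all others, and short reads shared by copies of a gene family are split in a way the values do not show. The score of each Tbx3 site is the deposited peak score; its lowest value and the site names are those of MACS, while the processing notes name HOMER and Bowtie 1.0, and which made the score is not given in the sources used here. Tool versions other than Bowtie are not given. The bulk table lists 11647 genes by a filter that is not given, 18 of them with a date in place of a name, and 185 with a 0 in at least 1 library.

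From these values log2((a + 1)/(b + 1)) was computed per gene for 4 comparisons, with a pseudocount of 1 and genes at 1 FPKM or more in at least 1 of the 2 libraries. Genes with a difference of 2-fold or more on that scale were counted. As 1 library stands for each group, no p-value is given across genes. The median of each of 23 gene lists was placed among 10000 random lists of the same size and expression (20 bins), and lists below percentile 2.5 or above 97.5 were called outside; at least 3 measured members were needed. Tbx3 was left out of every list. These choices were made before the data were examined. A list of 26 interferon-stimulated genes and 1 of 19 B-cell and antigen presentation genes were written after the differences had been seen. Differences against a shared library were set beside 100 simulated pairs of unchanged libraries.

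The genes named were chosen by a fixed rule, and some that it gives are not named. Tbx3 and Dppa3 were always named. Each comparison gave the 10 largest positive and 10 largest negative differences among genes at 5 FPKM or more in either library, without predicted models and small RNAs, and up to 4 members of each list with the largest change. Knockout and knockdown together gave the 10 largest shared differences each way, the sites the 10 highest scores and those within 20 kb of a list gene, and the cells the 10 highest and 10 lowest correlations with Tbx3 and the list genes. Pou5f1, Nanog, Sall4 and Zfp42 are list genes, and Cox19 was named after its values were seen.

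Sites were placed on the annotation of the same build (37252 genes, 22350 protein-coding). Of the 11647 names 11340 (97.4%) matched a gene. Shares near gene starts were compared with 100 random placements. Nearness to changed genes was tested with two-sided Fisher's exact tests on genes at 1 FPKM or more, adjusted over 4 tests by Benjamini-Hochberg. Sequence matches in sites were compared with flanks of equal width 2 kb away by an exact McNemar test for 9 sequences, and with 100 rearrangements of the letters. Cells were counted at 1 FPKM with exact Clopper-Pearson 95% intervals. Correlations were tested by permutation with 100000 resamples, and genes in at least 25% of cells were scanned. Fragments per cell are not given; a relative depth read from the steps between the lowest values ran from 0.143 to 1.61, with medians of 1.22 and 0.634 in the blocks of columns, so most cells of the second block carry less precise values.

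Each calculation was tested on simulated data. With 200 genes changed among the 11382 genes of N/N against +/+, 100% of 4-fold changes passed 2-fold and 41% of those exactly 2-fold, and 0 unchanged genes did. Changed genes were at 5 FPKM or more and the simulated noise had the same size at every level. The 0 therefore does not give the error rate of the real libraries. In the cell scan 100% of 200 planted genes were recovered and 5 unplanted genes were called among the 3062 run. The planted genes followed Tbx3 more closely than any real gene (highest rho 0.52), so recovery of weaker relations was not tested. In the site test 1 of 50 shuffles fell under 0.05 and a planted relation gave an odds ratio of 6.27, over 11179 genes. Alternatives changed the pseudocount (0.1 and 5), the fold (1.5), the filter, the scaling, the window (5 and 50 kb), the set of sites and the cells. No column was left without a sample (0 columns). Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Reads were not analysed here.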

Results

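Tbx3 is a T-box transcription factor of mouse embryonic stem cells, and Dppa3 (also called Stella) is a maternal-effect gene that marks a part of such cells. RNA was sequenced from 5 populations of R1 embryonic stem cells, a line of the 129 strain. They were cells with 2 intact Tbx3 alleles (+/+), with 1 targeted allele (+/N) and with both targeted (N/N), and cells with a hairpin against Tbx3 (shTbx3) or against luciferase (shLuc). Each population had 1 library, so no difference between them has a replicate check. Another data set listed 3078 genomic sites bound by biotin-tagged Tbx3, and a single-cell table held 45 cells and 1 pool of cells sorted for the surface antigen SSEA1. The bulk table listed 11647 genes, with a median of 9.13 to 10.6 FPKM per library. Read depth is not given in the sources used here.

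The targeted gene was read first. Tbx3 stood at 44.4 FPKM in the +/+ library, at 22.5 FPKM (50.7%) in +/N and at 15.1 FPKM (34.0%) in N/N. In the hairpin pair it was 13.8 FPKM in shLuc and 5.09 FPKM (36.9%) in shTbx3. Dppa3 ran in the opposite order within each set of libraries. It was 5.32 FPKM in +/+, 8.95 in +/N and 24.7 in N/N, and 29.1 in shLuc and 51.3 in shTbx3. The allele and hairpin sets differed broadly: Pearson r of log2(FPKM + 1) was 0.955 to 0.982 within a set and 0.790 to 0.806 between them. Small RNA genes held 19.5% to 22.4% of the summed FPKM in the allele set and 5.31% to 7.14% in the hairpin set. The 5 libraries are thus not a single series of Tbx3 levels. The labels do not say which part of Tbx3 was deleted, so the values do not show how much functional transcript remained in N/N. The shLuc library read lower for Tbx3 than the N/N library, but that comparison crosses the sets. How far the starting levels of the pairs differed is therefore not known.

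**Figure D1:**
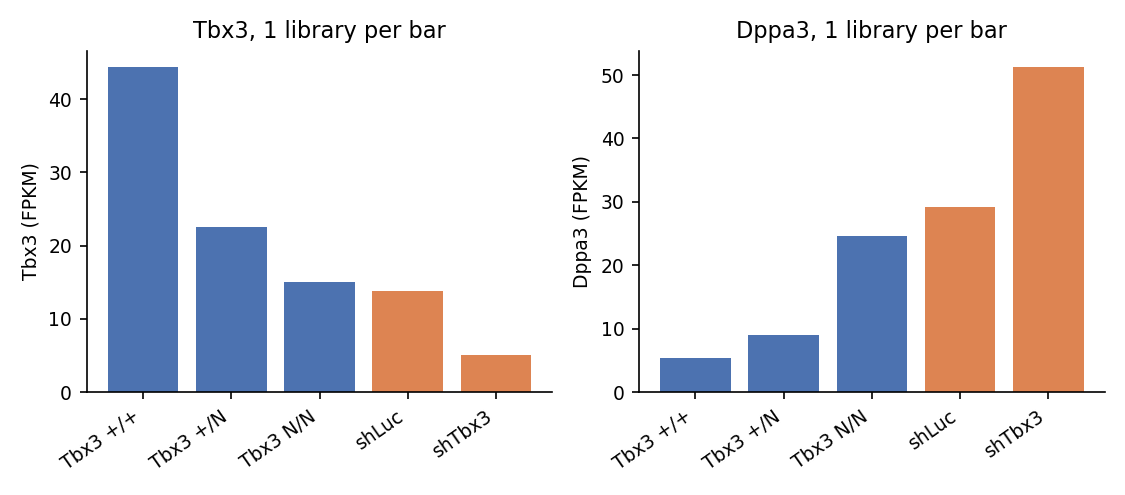
Tbx3 (left) and Dppa3 (right) in FPKM in the 5 bulk libraries, 1 bar per library, with the targeted alleles in blue and the hairpins in orange. Tbx3 was highest in +/+ at 44.4 FPKM and lowest in shTbx3 at 5.09 FPKM, and Dppa3 was lowest in +/+ at 5.32 FPKM and highest in shTbx3 at 51.3 FPKM. The blue and orange bars are separate sets of libraries.

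The comparison of N/N with +/+ addressed what the loss of both intact alleles goes with. Among the genes with the largest positive differences, Mgp, an inhibitor of calcification, was at 1.84 FPKM in +/+ and 18.4 in N/N, and Acta2, smooth muscle actin, at 3.31 and 28.1. Lox, which crosslinks collagen, was 5.96-fold higher, Tagln 4.02-fold and Dppa3 4.63-fold. The stress factor Ddit3 (11.9 and 45.1 FPKM), Fam183b, Npcd and the ribosomal RNA precursor Rn45s were also among the 10 largest positive differences. Interferon-stimulated genes were lower in N/N: Usp18 at 37.3 FPKM in +/+ and 2.66 in N/N, Isg15 at 53.9 and 4.33, Irf7 at 32.04 and 2.89, and Irgm1, Xaf1, Oas2 and Rtp4 lower by a log2 of -2.99, -2.80, -2.44 and -2.39. Basement membrane collagens Col4a1 (35.1 and 3.75 FPKM) and Col4a2 (20.5 and 2.73) and the proteoglycan Srgn (6.54 and 0.253) were also among the 10 largest negative differences.

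Of the 12 measured endoderm genes, all were lower in N/N than in +/+ and 8 at least 2-fold. They included Lama1, Cubn, Gata6 and Dab2, and their median log2 difference of -1.56 lay below all of 10000 random lists matched on size and expression. The naive pluripotency list lay lower too (median -0.32, percentile 0.08), with Klf4 (88.9 FPKM in +/+ and 36.5 in N/N) and Gbx2 (12.0 and 5.41) at least 2-fold lower and Dppa3 the 1 member at least 2-fold higher. The formative list was lower (median -0.43, percentile 0.16; Sox3 4.995 and 1.499 FPKM), although Otx2 (log2 0.52) and Dnmt3b (0.50) were higher. Without the filter on expression, an alternative chosen after seeing the data, its median was -0.27 (percentile 2.06). The list of 2-cell-stage genes was lower too (5 measured, median -1.01, percentile 0.01; Zscan4d 4.29 and 0.786 FPKM). Higher in N/N were the imprinted genes (median 0.33, percentile 99.98; 12 of 18 higher and 6 lower, with Igf2 at 4.24 and 16.4 FPKM and Phlda2 at 61.97 and 27.5), the fibroblast markers (median 0.99 over 8 genes, above all random lists; Col1a1 14.7 and 34.3 FPKM) and ribosomal protein genes (median 0.30, percentile 99.35). The core pluripotency factors lay inside the random range (median -0.02, percentile 48.8), with Pou5f1 at 660 and 532 FPKM and Nanog at 71.6 and 59.9.

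Of the other lists, the primitive streak and mesoderm genes (6 measured, median -0.05, percentile 52.3), neuroectoderm (percentile 16.9), trophectoderm (90.1), germline (76.3) and DNA methylation genes (27.1) lay inside the random range in this comparison. So did p53 targets (percentile 87), LIF and Stat3 targets (9.34), Wnt targets (66.6), Nodal targets (13.8), BMP targets (45.4), hypoxia and glycolysis genes (97.0), heat shock and immediate-early genes (5.14), cell cycle genes (90.3) and housekeeping genes (86.5). The cardiac list had 2 measured genes, too few for a median. Among 11478 genes at 1 FPKM or more in either library, 157 were at least 2-fold higher and 220 lower in N/N on the scale of log2(FPKM + 1), which understates the folds of genes near 1 FPKM. Without small RNA genes, a filter chosen after seeing the data, the counts were 126 and 164. About 5% of lists of randomly drawn genes fall outside the middle 95% by construction. Genes of a fixed list can vary together, and the random range does not measure the spread between libraries. A list outside it is therefore a description of these libraries, with no known error rate.

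In the +/N library, with 1 targeted allele, interferon genes were again low: Isg15 at 53.9 FPKM in +/+ and 3.66 in +/N, Usp18 at 37.3 and 3.27, and Irf7, Irgm1, Rtp4, Oasl1, Xaf1, Oasl2 and Oas2 lower by log2 differences of -3.07 to -2.06. Amn, an endoderm gene, was 7.48 and 1.12 FPKM. Higher were Mgp at 1.84 and 29.3 FPKM, Acta2 at 3.31 and 19.3, Bgn at 12.2 and 47.5, Cav1 at 0.681 and 5.16, and Lox, Igf2, S100a4, Postn and Fam183b by 1.54 to 1.75 on the log2 scale. The endoderm list (median -1.17, 12 of 12 genes lower) and 2-cell list (-0.57, percentile 0.06) were lower. The fibroblast (1.04), imprinted (0.33), Wnt (0.30, percentile 98.9), hypoxia and glycolysis (0.09, percentile 99.4) and ribosomal protein (0.08, percentile 97.9) lists were higher than the random range, and the other lists with at least 3 measured genes lay inside it. The median of genes at 5 FPKM or more in both libraries was shifted by -0.12 in this comparison, so values are to be read relative to it.

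Among 11459 genes, 80 were at least 2-fold higher and 139 lower in +/N. Setting the shifted median to 0 turned this into 106 and 118, and without small RNA genes the counts were 54 and 81. The +/N and N/N differences, both taken against the 1 +/+ library, ran together across 11492 genes (Pearson r 0.770, Spearman rho 0.856). Without small RNA genes r was 0.888, beside 0.501 for simulated unchanged libraries that shared such a control, and the covariance was 0.113 beside 0.0172. In that set 43 genes were at least 2-fold higher in both and 74 lower in both, beside 0.05 and 0.76 in the simulation. Whatever set the +/+ library apart counts in both differences, so these numbers do not show an effect of the targeted alleles.

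The N/N and +/N libraries were compared without the +/+ library. Dppa3 was 2.75-fold higher in N/N (8.95 and 24.7 FPKM), with larger differences for the X-linked homeobox genes Rhox9 (4.90 and 16.2) and Rhox6 (6.04 and 19.09). Wnt7b, Aif1l, Gstm3, Rab25, Espn, Cd164l2 and Calml4 followed at log2 differences of 0.89 to 1.11. The imprinted growth regulators Phlda2 (63.8 and 27.5 FPKM) and Cdkn1c (13.3 and 6.98) were lower, as were Col4a1, Lama1, Rpph1, Sox4, Cmklr1, Ngfr, Prmt8 and Foxd3, by log2 differences of -0.97 to -0.72. Counts at 2-fold were 36 higher and 35 lower of 11362 genes, and 7 and 2 without small RNA genes.

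In this comparison the lists below the random range were endoderm (median -0.38), naive (-0.10) and core pluripotency (-0.04), formative (-0.18), Nodal targets (-0.15), fibroblast (-0.18), imprinted (-0.02), LIF and Stat3 targets (-0.03), heat shock and immediate-early genes (-0.03) and p53 targets (0.02). The trophectoderm list lay above it (0.25, percentile 99.5; Krt18 16.4 and 28.4 FPKM). The remaining lists lay inside the range or had fewer than 3 measured genes. The p53 list had a positive median, read against a median of 0.09 over genes at 5 FPKM or more in both libraries.

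The hairpin comparison showed another set of genes. Primitive streak genes were higher in shTbx3: T (Brachyury) at 0.605 FPKM in shLuc and 35.5 in shTbx3, Fgf8 at 0.320 and 25.4, and the Wnt target Sp5 at 0.740 and 26.0. All 9 streak and mesoderm genes of the table were higher and 7 at least 2-fold, with Wnt3 (0.153 and 5.36 FPKM), Hand1 and Eomes among these. The filter kept the 7 (median log2 2.36, above all random lists), of which Eomes alone was above 1 FPKM in shLuc (1.25), so 6 entered by their shTbx3 level. Without the filter the median over 9 genes was 1.72, also above all random lists. Keratins were higher as well, Krt8 at 10.3 and 167 FPKM, Krt18 at 13.4 and 140 and Krt19 at 8.07 and 100, with Igfbp3, Cyr61, Igf2 and Cyp26a1, a retinoic acid hydroxylase. Genes of antigen-presenting and B cells were lower: Cd52 at 14.7 and 0.497 FPKM, H2-Ab1 at 21.8 and 1.61, Cd74 at 30.9 and 2.85, with H2-Eb1 and Cd79b. Rpl39l, Lrrc34, A2m, Zscan4a and Mlana were lower too. The median over genes at 5 FPKM or more in both libraries was shifted by 0.16, and the list values are to be read against it.

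Other lists above the random range in shTbx3 were Wnt targets (median 1.42, 4 of 6 genes at least 2-fold higher), BMP targets (1.34; Id3 13.2 and 89.6 FPKM), fibroblast markers (1.07, or 0.63 at percentile 99.9 without the filter), heat shock and immediate-early genes (0.82), imprinted genes (0.73, 17 of 18 higher), trophectoderm (0.55), LIF and Stat3 targets (0.53) and p53 targets (0.45, percentile 98.7). These lists are not separate evidence where they share genes: T and Cdx1 are Wnt and streak genes, Hand1 is a streak and trophectoderm gene, and Fos and Junb are LIF and immediate-early genes. The other Wnt targets were Sp5 (log2 3.96), Axin2 (1.26), Tcf7 (0.29) and Lef1 (0.13). The 2-cell list (-1.14, all 4 genes past the filter lower; Zscan4d 4.49 and 1.04 FPKM) and the hypoxia and glycolysis list (-0.30; Bnip3 32.2 and 10.7) were lower. Core (0.01) and naive pluripotency (0.38), formative (0.26), endoderm (0.38), neuroectoderm (0.20), germline (0.00), DNA methylation (0.07), Nodal (0.21), cell cycle (0.18), ribosomal protein (-0.04) and housekeeping genes (0.09) lay inside. Within them Otx2 (29.4 and 11.2 FPKM) and Pecam1 were lower and Gbx2 (7.91 and 24.4) and Klf5 (38.7 and 80.6) higher. Among 11342 genes 319 were at least 2-fold higher and 112 lower, or 219 and 171 once the median was set to 0.

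**Figure D2:**
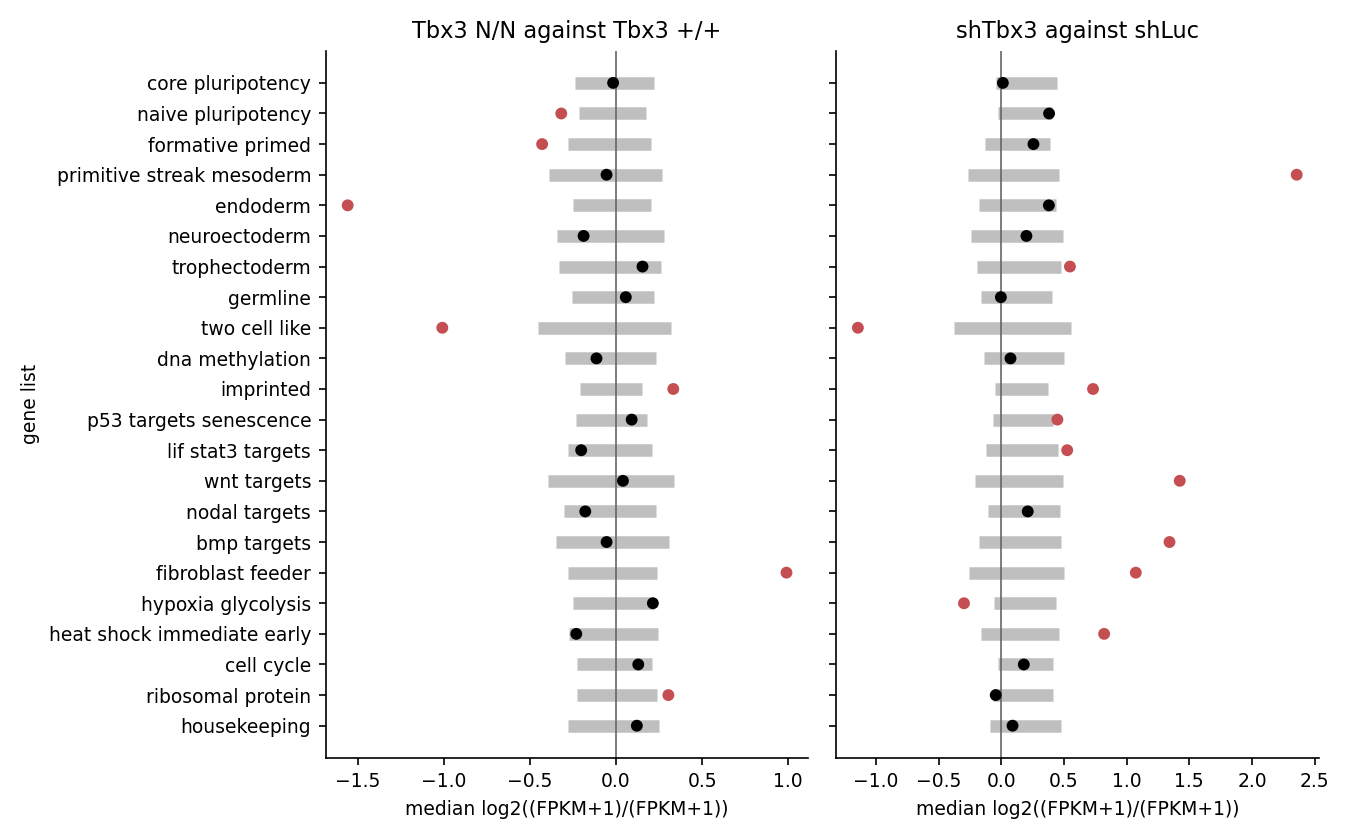
Median log2 difference of each fixed gene list (points) in N/N against +/+ (left) and shTbx3 against shLuc (right), with grey bars for the middle 95% of 10000 random lists of matched size and expression and red for points outside them. Endoderm genes lay at -1.56 on the left and primitive streak genes at 2.36 on the right.

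Targeted alleles and hairpin were then set against each other. Genes higher in both N/N and shTbx3 included Acta2, Tagln, Igf2, H19, S100a13, S100a1, S100a11, Thbs1 and Lgals1, with Tagln at 7.86 and 31.6 FPKM in +/+ and N/N and at 13.7 and 106 in shLuc and shTbx3. The fibroblast and imprinted lists were above the random range in both and the 2-cell list below it in both. The fibroblast members behind this were shared in part. Acta2 (log2 2.75 in N/N and 2.40 in shTbx3), Col1a1 (1.17 and 2.16) and S100a4 (1.08 and 0.59) were higher in both. Others differed: Postn and Col1a2 stood at 8.60 and 14.7 FPKM in N/N but at 0.0164 and 0.204 in shTbx3. Thy1 was lower in shTbx3 (log2 -0.82). Lower in both were Ifi27l2a, Inhbb, Crtac1, Kdelr3, Cmklr1, Atp2a3, D1Pas1, Xaf1, Fgf15 and Prph. Across 11637 genes the signed differences showed almost no linear or rank relation (Pearson r 0.004, Spearman rho -0.07), and genes are not independent replicates. At 2-fold, 25 genes were higher in both (4.30 for independent lists) and 15 lower in both (2.09). Another 15 were lower in N/N and higher in shTbx3 (6.003), and 4 the reverse (1.498). Every pairing of directions exceeded its value for independent lists, so the overlap in the same direction does not by itself show agreement.

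Tbx3 binding was described from 3078 sites on mm9, whose score ran from 50.01 to 791. Sites lay near gene starts: 52.3% were within 20 kb of the start of a protein-coding gene and 19.2% within 1 kb, against 25.9% and 2.15% in random placements. By annotation of all genes, coding or not, 21.6% were promoters, 34.1% introns, 3.09% exons and 41.2% intergenic. The sites with the highest scores, named by the nearest start of a coding gene, were 37930 bp from that of Larp1 (chromosome 11, 57784021 to 57784636, score 791), 420 bp from that of Mycn (chromosome 12, 12949140 to 12950741, 746) and 11331 bp from that of Sars (chromosome 3, 108236287 to 108236796, 723), followed by those nearest Sulf1, F730048M01Rik, Klf9, Spen, Ly86, B3gnt7 and Hsd17b14. Among autosomes, chromosome 11 held the most sites per 100 Mb (190) and chromosome 8 the fewest (95.6), and the X chromosome held 34.8. R1 cells are male, so the X was present once, and whether that accounts for its lower density was not tested.

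A site of score 411, rank 46, lay 1400 bp upstream of the Dppa3 start (site at chromosome 6, 122574284 to 122575028; Dppa3 from 122576428 to 122580290 on the plus strand). It held 2 copies of the octamer in the orientation ATTTGCAT (122574655 to 122574662 and 122574699 to 122574706) and no match to the T-box core sequence GGTGTGA. Downstream, Nanog (122657507 to 122664651) had a site over its start (score 110) and another 4585 bp upstream (56.4). Of 256 placed list genes, 57 had a site within 20 kb, among them Pou5f1 with 4 sites, Sox2, Tdgf1 (score 418), Id3 (489), Klf2 (253), Lefty1 (282), Tet1, Tet3 (358) and Peg3 (534). Tbx3 itself had a site just inside its start (chromosome 5, 120120686 to 120121148, score 69.8).

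**Figure D3:**
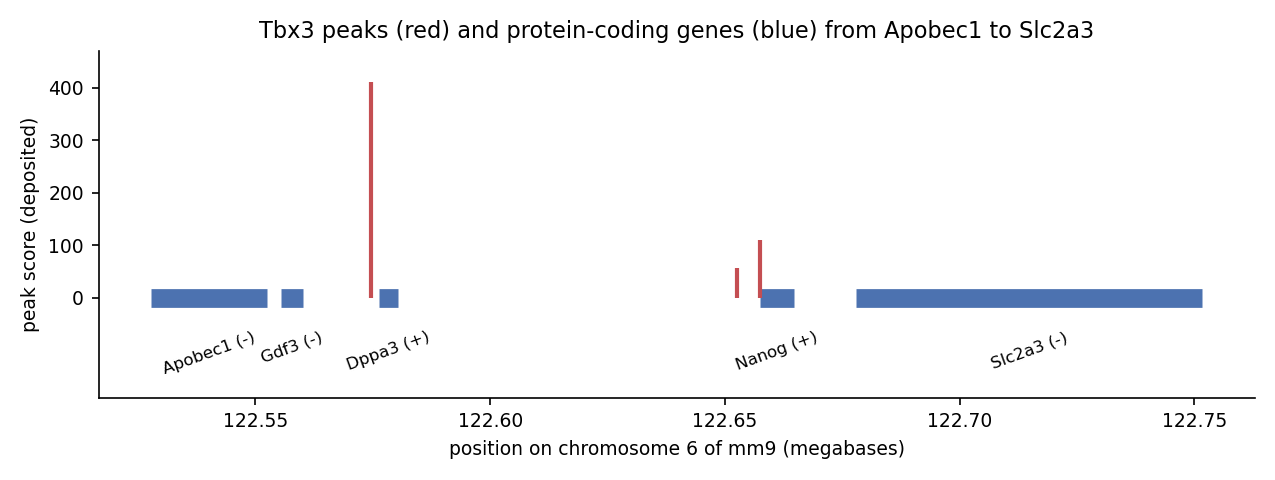
Tbx3 sites (red lines, height is the deposited score) and protein-coding genes (blue) on chromosome 6 of mm9, from Apobec1 to Slc2a3, with position in megabases on the x axis. The site upstream of Dppa3 scored 411, and those at Nanog 110 and 56.4.

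Sites were set against the expression differences. Genes at least 2-fold higher in shTbx3 had a site within 20 kb in 62 of 311 cases (19.9%), against 14.8% of the other genes (odds ratio 1.43, two-sided Fisher's exact p = 0.0154, adjusted 0.0615 over 4 tests). For genes higher in N/N the shares were 20.98% and 14.96% (odds ratio 1.51, p = 0.0583, adjusted 0.117), for genes lower in N/N 13.9% and 15.1% (p = 0.761) and for genes lower in shTbx3 13.3% and 14.97% (p = 0.783). None passed 0.05 after Benjamini-Hochberg adjustment. The hairpin result passed with a 50 kb window (adjusted p = 0.0134) and with the sites of higher score (odds ratio 1.82, adjusted p = 0.00533), within a range of 0.00533 to 0.409 over its alternatives. All 4 tests used the differences without setting the median shift, 0.16 in the hairpin pair, to 0. Fewer genes were at least 2-fold higher in shTbx3 after that step, and the site tests were not repeated on them. Genes are not independent replicates, and each comparison rests on 1 library per side.

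In single SSEA1-positive cells, Tbx3 was at 1 FPKM or more in 13 of 45 cells (28.9%, exact Clopper-Pearson 95% interval 16.4 to 44.3), and Dppa3 in 10 (22.2%, 11.2 to 37.1). The highest cell held 117 FPKM of Tbx3 and another 1036 FPKM of Dppa3, and 2 cells had both, beside 2.89 under independence. The cells fell in 2 blocks of columns, 23 and 22 cells, which are places in the table and not a label; the median number of genes at 1 FPKM or more was 2446 in the first and 1973 in the second. Tbx3 was present in 6 cells of the first and 7 of the second block, and Dppa3 in 7 and 3. Spearman's rho between Tbx3 and Dppa3 was -0.06 (permutation test, two-sided p = 0.713), with -0.13 and -0.004 within blocks. Pearson's r on the log scale was -0.22 (permutation p = 0.148, or -0.19 without the 2 farthest cells), with -0.27 and -0.15 within blocks. None of the 6 correlations passed adjustment (lowest adjusted p = 0.706). The intervals cover counting error only, and the absence of a detectable relation does not show that there is none at this number of cells.

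**Figure D4:**
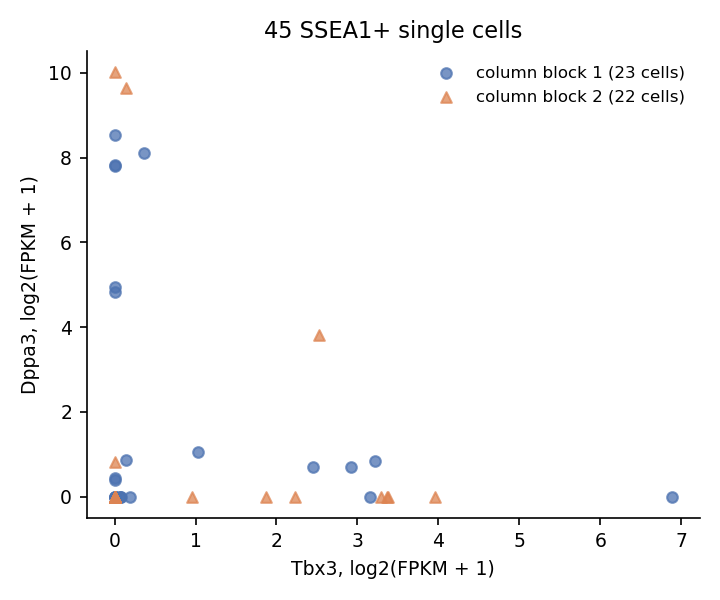
Dppa3 against Tbx3 in 45 single cells, both as log2(FPKM + 1), with circles and triangles for the first (23 cells) and second (22 cells) block of columns. Most cells lie on an axis, and 2 cells were at 1 FPKM or more for both genes.

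Across 3061 genes present in at least 25% of cells, none varied with Tbx3 past a Benjamini-Hochberg value of 0.05 by permutation test, and 182 had an unadjusted p under 0.05 where chance gives 153. The highest rho was Elof1 (0.52), followed by Nop56, Zbtb44, Cbx7, Aqp3, Me2, Snora43, Wee1, Srsf2 and Cops8. The lowest was Abcb10 (-0.43), and the 10 lowest also included Brd7, Cd24a, Utf1, Thoc2, Aggf1, Irak1, Eif4ebp1 and Rpl13. Of 75 list genes tested, 0 passed when adjusted over the list alone (lowest 0.275) and 7 had an unadjusted p under 0.05, with Klf4 at 0.37, Tet2 at 0.43 and Utf1 at -0.38. The Tbx3 and Dppa3 pair was at percentile 25.1 of all rho. With Dppa3, 2 of 3062 genes passed (adjusted p = 0.0306), among them Cox19, a mitochondrial copper protein (rho 0.62, with 0.34 and 0.75 within blocks).

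The mean of the cells and the pool correlated across genes (Pearson r 0.815, in log2; the blocks gave 0.785 and 0.772). Several pluripotency genes did not match between them: Pou5f1 was at 1370 FPKM in the pool and at 1 FPKM or more in 24.4% of cells, while the 200 genes nearest in pool level had a median of 95.6%. Nanog was at 287 FPKM and in 26.7% of cells, whereas Sall4 was at 72.4 FPKM and in every cell (mean 3337 FPKM). Zfp42 matched, in every cell at a mean of 639 FPKM and at 502 FPKM in the pool. Mismatch was not limited to pluripotency factors, as Actb had a mean of 19751 FPKM in the cells and 1108 in the pool. Tbx3 had a mean of 4.45 FPKM in the cells and 25.8 in the pool, and Dppa3 of 66.7 and 12.8. The shares of cells with Tbx3 and Dppa3 and their correlation are to be read with that limit. Tbx3 ranked 140 of 201 by squared coefficient of variation among genes of like mean, and Dppa3 20 of 201. Of the markers of other types fixed beforehand, T, Col1a1, Dab2 and Cdx2 reached 1 FPKM in 0 of 45 cells, Mixl1 in 3, and Eomes, Thy1 and Gata3 in 1 each. In the wider lists of such types, Tubb3 did so in 17 cells, Ncam1 and Sparc in 11 each, Tfap2c in 10 and Vim and Lamc1 in 9 each. Shallow cells can miss transcripts, so these counts do not bound the share of cells of another type.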

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

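The tests of the interferon and immune genes were chosen only after the results were seen, and those of the interferon genes were revised once more after that. The following 13 list genes went one way in the targeted alleles and the other with the hairpin, and that difference was not tested, as each rests on 1 library per side. Lower in N/N and higher in shTbx3 were the pluripotency factors Klf4 (log2 -1.26 and 0.59), Klf5 (-0.88 and 1.04), Gbx2 (-1.03 and 1.51) and Nr0b1 (-0.71 and 0.90), and Sox3 (-1.26 and 0.66). The immediate-early genes Atf3 (-1.10 and 0.91), Ier2 (-0.97 and 0.86) and Junb (-0.79 and 0.82) did the same, as did the BMP target Id1 (-0.78 and 1.28), the cell cycle genes Ccnd1 (-0.75 and 0.72) and Pcna (-0.59 and 0.72) and the laminin Lamc1 (-0.65 and 0.71). Sycp3, of the meiotic chromosome axis, was higher in N/N and lower in shTbx3 (1.00 and -1.39). Among list genes at this size 16 went the same way in both.

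Interferon-stimulated genes were highest in the +/+ library. Over 17 measured members of a list of 26 the N/N against +/+ median was -1.999, and -1.97 once the library median was set to 0, which argues against scaling. A response in proportion to total Tbx3 RNA on the log scale would predict a median of -0.73 in N/N against +/N. That RNA differed by -0.55 there. The median was -0.031 (quartiles -0.22 and 0.18), which argues against that form. Total RNA includes what the targeted alleles still make, so a response graded with functional Tbx3 was not tested. The hairpin pair excludes nothing, because shLuc already read lower for Tbx3 RNA than +/N, and these libraries belong to different sets. In that pair a first version over 11 members at 1 FPKM or more gave 0.17. A later version over the 7 at 5 FPKM or more, with room to fall, gave -0.05. Of the members, Isg15 (0.526 and 9.10 FPKM) and Irgm1 (1.37 and 8.37) were higher in shTbx3, and Xaf1 (log2 -0.84) and Ifi27l2a (-1.59) lower. All 17 (100%) were highest in +/+, so an interferon response of that culture and a response that needs the Tbx3 level met there alone cannot be told apart with 1 +/+ library.

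Genes of B cells and antigen presentation were high in shLuc. Of 12 measured members of a list of 19, 9 (75%) were at least 2-fold higher there than in shTbx3, and Cd52, Cd74 and H2-Ab1 stood at 14.7, 30.9 and 21.8 FPKM. RNA of such cells in the shLuc culture may be a source. Laptm5, abundant in such cells, was 16.5 FPKM in shLuc and 18.8 in shTbx3, but at 24.3 FPKM in +/+ its own baseline would hide a small share, and no sort against such cells is described for these libraries. The median in N/N against +/+ was 0.069, but it rests mostly on members near the floor. Laptm5 was the 1 member that reached 5 FPKM in +/+, and it was lower in N/N (14.0 FPKM, log2 -0.75). That is too few to decide whether lower Tbx3 lowers these genes. These remain open and cannot be told apart.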

How the results depend on the processing

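The small RNA filter, the lists without a filter, single blocks of cells, the site tests without Tbx3 and the site tests on lists were chosen after seeing the data. No paired analysis was possible because each bulk group had 1 library. Of 525 alternative values over 139 results 495 kept their direction and their side of the threshold, or, for counts and values with no test, stayed within the limit set for a change; without the filter every list median stayed inside or outside the random range as before; resetting the scale cannot move a list percentile by construction. With a pseudocount of 0.1 the 2-fold counts were 620 (N/N against +/+), 349 (+/N against +/+) and 751 (hairpin), and with 5 they were 165, 119 and 137. At 1.5-fold they were 1368, 843, 202 (N/N against +/N) and 1866. Without small RNAs +/N against +/+ gave 135 instead of 219, and N/N against +/N 9 instead of 71. Only 192 and 181 genes were left out, so small RNA genes held most of the 2-fold differences in N/N against +/N. The p53 list in N/N against +/N turned to -0.074 when the median was set to 0, by construction of that scale. Sites of the higher-scoring part lay within 20 kb of a gene start in 50.5%. The share within 1 kb fell with score, from 19.2% of all sites to 15.9% of that part and 12.7% of the 307 highest. For genes higher in shTbx3 the odds ratio passed adjustment with 50 kb (1.44) and with the higher scores (1.82). The median of cells correlated with the pool at 0.488, and Tbx3 ranked 90 in variability in the first block of cells alone. Where no construction is named, the cause was not tested. Tbx3 was at any value above 0 in 46.7% of cells and at 10 FPKM in 4.44%, so its share depends on the limit, and shallow cells limit it.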

Other observations

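The site tests on gene lists and the letter rearrangements were chosen only after the results were seen; the T-box and octamer tests were set before the sequences were counted. Tbx3 sites gathered at the core pluripotency and Nodal genes. Of 11 core pluripotency genes 9 had a site within 20 kb, against 14.8% of other genes (odds ratio 25.8, two-sided Fisher's exact p = 1.48e-06, adjusted 3.26e-05 over 22 lists). Of 8 Nodal pathway genes 7 had one (odds ratio 40.1, adjusted p = 0.000124, and 1.36e-06 to 0.0945 over its alternatives, the last with a 5 kb window), and Tdgf1 is in both lists. The site counted for Gdf3 is the one 1400 bp upstream of Dppa3, 14179 bp from the Gdf3 start. Within 5 kb 3 of the 8 Nodal genes had a site. No other list passed, among them the naive (5 of 14, adjusted p = 0.201) and formative lists (5 of 11, 0.113). With the higher-scoring sites alone DNA methylation (0.0123), naive (0.0141), formative (0.0290) and BMP genes (0.0421) passed as well, and with a 50 kb window LIF and Stat3 targets (0.0145). Expression of the core and Nodal lists in N/N lay inside the random range against +/+ and below it against +/N (percentiles 0.18 and 0.01). Endoderm (0 of 11), fibroblast (0 of 8), housekeeping (0 of 8), trophectoderm (0 of 6) and 2-cell genes (0 of 4) had no site within 20 kb, and none of these counts passed a test against the other genes.

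Sequences under the sites were counted. The T-box core sequence was in 13.5% of sites and 7.15% of flanks (ratio 1.89, exact McNemar p = 2.61e-16). Direct contact would give such a ratio, but the KLF sequence GGGTGTGG shares the letters GGTGTG with the T-box core and was enriched too. The counts do not tell T-box sites from sequences of that kind. The octamer of POU factors was in 8.45% and 3.41% (ratio 2.48), and the SOX, Esrrb and KLF sequences were enriched too (ratios 1.25, 2.72 and 2.08), which is consistent with binding beside those factors. The E-box was enriched too (1.39), CTCF and AP-1 did not pass (1.79, p = 0.108, and 1.02, p = 0.827), and a control sequence was lower in sites (0.746), among 9 sequences tested. Sites had more GC (51.4% against 44.9%), but of 100 rearrangements of the T-box letters 1 reached its ratio, with 0 of 100 for the octamer and 2 of 100 for Esrrb. Base composition of the peaks alone therefore does not explain the ratios of these sequences. The SOX, KLF and E-box sequences had no such control.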
